A study of Mus musculus with 18 samples.

How the data were processed

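Whole lungs of 18 mice were measured on Affymetrix Mouse 430 2.0 arrays, 1 array per mouse, in 6 groups of 3 formed by strain (A/J or C57BL/6) and treatment (PBS aerosol, ovalbumin aerosol, or resiquimod before ovalbumin aerosol). Total RNA was extracted from homogenized lungs and labelled with biotin per the labels' protocols. The labels call the samples of a group biological replicates, and each sample is taken as 1 mouse. The p-values measure only the spread between these samples.

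The deposited table holds log2 expression values made by the authors with RMA (robust multi-array average), which corrects background, normalizes quantiles between arrays and summarises probes to probe sets. RMA and the affy package are named in the submitters' processing notes, which give no version. The unit was checked on the values, which run from 2.00 to 14.03 with array medians between 4.77 and 4.80, as RMA output on the log2 scale does. The table has 45101 probe sets and no filter, and all 18 columns were used. Within groups arrays correlated with Pearson r from 0.987 to 0.997 across probe sets, which are not independent replicates, and no pair of arrays was identical. The 25th percentile of all values was 3.33, the median 4.79 and the 75th percentile 6.86, so a gene near 3.33 lies among the weakest signals, where a fall would be hard to see. The files give no scan date or batch.

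After 64 Affymetrix control probe sets were left out, 45037 were tested. The probe annotation pairs 34945 of them with 1 gene, 932 with several and 9160 with none, and the gene names of 34741 of the 34945 have a RefSeq entry with the same Entrez identifier. A gene is represented by the probe set with the highest mean over the 18 arrays among those that name that gene alone, which gives 18193 genes. Genes named only together with others were not given values.

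Values were fitted with limma 3.58.1 in R 4.3.3 as 6 group means (lmFit, 12 residual degrees of freedom), moderated with eBayes (prior degrees of freedom 4.30) and tested two-sided with limma's moderated test. P-values were adjusted by Benjamini-Hochberg over the 45037 probe sets of a comparison, and a probe set was called at an adjusted p under 0.05. The 4 main comparisons were ovalbumin against PBS and resiquimod with ovalbumin against ovalbumin, each in either strain. The others were resiquimod with ovalbumin against PBS in either strain, A/J against C57BL/6 in the PBS groups, and the difference between strains in the ovalbumin and in the resiquimod effect. All differences are on the log2 scale, in the order named, and A/J minus C57BL/6 for strains.

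The comparisons, the tests, the alternatives, the rule for named genes and 40 gene lists were chosen before the data were examined. The lists cover immune cell types, lung cell types, immune pathways, matrix and remodelling, handling and other tissues, with 664 of 724 members measured, some of them in more than 1 list. Each list was tested with limma's camera at a preset correlation of 0.01 between genes, with Benjamini-Hochberg over the 40 lists of a comparison, and beside it with camera at an estimated correlation and with fry. Camera compares a list with the other genes, while fry asks whether a list's genes move on balance 1 way. Members passing the test were counted over all probe sets and adjusted over the list alone.

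Named genes are, for each main comparison, the 10 with the largest rise and the 10 with the largest fall among called genes whose 3 arrays of 1 group all lie beyond the 3 of the other, up to 4 called members per gene list with the largest changes (or 2 members given as values where none was called), and always Tlr7, Il13, Il4, Il5, Ccl11, Muc5ac, Ifng and Cxcl10. In the other comparisons 5 and 5 genes were taken. Clone names, predicted genes and probe sets for several genes were passed over, and the text gives part of these genes in order of size.

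Genes called for ovalbumin in 1 strain were followed for resiquimod in the other strain, so that no array served both. Within a strain both comparisons use the ovalbumin arrays, so 50 simulated data sets gave the values that arise when the resiquimod group is drawn like the ovalbumin group or like the PBS group. Overlaps between strains are given beside the product of the list sizes divided by 18193. Array quality measures and list means were compared with exact two-sided permutation tests, which cannot go below p = 0.1 with 3 against 3 arrays.

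The pipeline was tested on simulated data of the same size and spread, with noise drawn independently for each probe set or gene. In the real arrays 1 component held 42.7% of the variance within groups, and the rates given here do not cover such shared variation. For a simulated ovalbumin effect in A/J over 45037 probe sets it recovered 56.7% of the changes of 0.5 log2, 95.5% of those of 1 and 98.5% of those of 2, with 11 false calls. For a simulated strain difference in the ovalbumin effect it recovered 22.4%, 80.6% and 98.5% with 4 false calls. Camera called the 1 shifted list, that of neutrophils, and 1 of 39 unshifted lists for the simulated ovalbumin effect in A/J, over 18193 genes. Some unshifted lists share a shifted member, such as Lcn2 in the acute phase list.

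Alternatives chosen beforehand were the replicate number as a block, a filter on low signal, centring each array on its median, a further quantile normalization, an intensity trend with robust moderation, array weights, leaving out probe sets marked _x_at or _s_at, the mean of a gene's probe sets, a fit to the compared groups alone, the estimated correlation, fry, and each array left out in turn. After the data were examined, lists of squamous epithelium, liver and stomach genes were written, and an array was taken to hold such transcripts when its list mean lay above the midpoint of the range over the arrays. The alternatives added at that point are the squamous transcripts as a block, a fit to the 10 arrays without them, a fit without the 3 arrays with liver or stomach transcripts, and the first principal component of the deviations within groups as a covariate. Adding that component leaves every difference between groups unchanged and alters only the residual spread. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.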

Results

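Gene expression was measured in whole lungs of 18 male mice aged 16 weeks, 9 of strain A/J and 9 of strain C57BL/6, with 1 microarray per mouse. Per the labels' protocols every mouse was sensitized to ovalbumin, an egg protein used as a model allergen, by 3 weekly intraperitoneal injections of 100 µg in alum. The mice were challenged by aerosol for 30 min on each of 3 days, beginning 7 days after the last injection. The 3 groups of each strain differed in what followed sensitization. The PBS group inhaled PBS, the ovalbumin group inhaled 1% ovalbumin, and the resiquimod group inhaled 1% ovalbumin after intraperitoneal injections of 100 µg resiquimod, a small-molecule agonist of Toll-like receptor 7 (Tlr7), given 24 h before each challenge. No group received resiquimod without ovalbumin, and the sample descriptions used here list no vehicle injection for the other groups. An effect of resiquimod itself can therefore not be told apart from an effect on the response to ovalbumin or of the injections. Each of the 6 groups held 3 arrays, and this number of arrays limits the precision of every value. The Affymetrix Mouse 430 2.0 array carries 45037 probe sets besides its controls, which stand for 18193 named genes, and the arrays give no genomic positions. Values are on the log2 scale, and changes are given as log2 change ± SE with n = 3 arrays per group. In whole lung, a change in the share of a cell type cannot be told apart from a change of expression within cells. This holds for every rise and fall given here. In each gene singled out by the size of its change in a strain, the 3 arrays of 1 group all lay beyond the 3 arrays of the other. Some genes sit in several of the gene lists, such as Ccl17, a chemokine of dendritic cells and alternatively activated macrophages.

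The first comparison asked which lung transcripts differ between A/J mice that inhaled ovalbumin and A/J mice that inhaled PBS. Ovalbumin challenge raised genes of mucus-producing cells, alternatively activated macrophages, chemokines and dividing cells in A/J lungs. Clca1 (Entrez Gene 23844), a secreted goblet cell protein that regulates mucus, rose 57.5-fold (log2 change 5.85 ± 0.48, n = 3 per group), from 7.04 ± 1.26 to 12.88 ± 0.06 (mean ± SD), and 93.0-fold in the fit without A/J PBS 3. Chil4 (Entrez Gene 104183), a chitinase-like protein of alternatively activated macrophages and airway epithelium, rose at least 58.1-fold (log2 change 5.86 ± 0.40, n = 3 per group). Its PBS values lay near the 25th percentile of all values (3.33), among the weakest signals, so folds from or to such values are lower bounds. The anion exchanger Slc26a4 (Entrez Gene 23985) rose 21.1-fold and Muc5ac (Entrez Gene 17833), a gel-forming airway mucin, rose 6.99-fold, with log2 changes of 4.40 ± 0.21 and 2.81 ± 0.24. Ccl11 (Entrez Gene 20292), the eotaxin that attracts eosinophils, rose 10.3-fold (log2 change 3.37 ± 0.22).

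By gene list, 15 of 19 measured mucus and goblet cell genes rose in A/J (16 when adjusted over the list alone), among them Itln1, a secreted lectin (3.76 ± 0.20), and Agr2, a disulfide isomerase needed for mucin assembly (3.31 ± 0.29). Of the alternatively activated macrophage genes 15 of 18 rose (18 adjusted over the list alone), including Rnase2a, an eosinophil-associated ribonuclease (5.12 ± 0.38), the C-type lectin Cd209e (3.58 ± 0.21) and the resistin-like Retnla (3.28 ± 0.13). Of the inflammatory chemokines 11 of 20 rose (12 adjusted over the list alone), such as Cxcl3, a neutrophil attractant (3.30 ± 0.45), the eotaxin Ccl24 (2.55 ± 0.15) and Ccl8 (2.54 ± 0.28). Cell cycle genes rose in 29 of 39 cases (35 adjusted over the list alone), with Top2a, a DNA topoisomerase (2.11 ± 0.16), and Birc5, a mitotic protein (2.11 ± 0.20), at the top. The macrophage and monocyte list had 10 genes higher and 1 lower of 22 (13 and 2 adjusted over the list alone), led by the elastase Mmp12 (2.56 ± 0.29) and the protease Ctsk (1.57 ± 0.18). Eosinophil genes rose in 5 of 11 cases (6 adjusted over the list alone), among them the granule proteins Prg2 (1.14 ± 0.15) and Epx (0.42 ± 0.08) and the cytokine receptor chain Csf2rb (0.90 ± 0.10). The dendritic cell list had 5 of 17 genes higher (6 adjusted over the list alone), among them the chemokines Ccl17 (2.50 ± 0.23) and Ccl22 (1.40 ± 0.10). The airway remodelling list had 5 of 18 higher (7 adjusted over the list alone), among them Timp1 (2.83 ± 0.15) and Serpina3n (1.51 ± 0.12).

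Among the type 2 cytokines and their receptors, 4 of 18 genes rose in A/J (5 adjusted over the list alone) and camera did not call the list (adjusted p = 0.0552). The alarmin Il33 rose by 1.30 ± 0.18, and Il13, the cytokine that drives goblet cell change, by 0.43 ± 0.11. The Il13 call was lost in 8 of the 18 fits that left out 1 array, and the call of Il4 (0.43 ± 0.11) in 11. Il5, the eosinophil growth factor, had a log2 change of 0.28 ± 0.09 and did not pass the test, nor did Tlr7 (0.06 ± 0.10) and Ifng (0.10 ± 0.28). The interferon-inducible chemokine Cxcl10 rose (2.10 ± 0.27). Smooth muscle genes moved with 6 higher and 1 lower of 14 (7 and 2 adjusted over the list alone), such as Actg2 (1.27 ± 0.13) and Tagln (0.57 ± 0.08), in a comparison where 2 of 3 ovalbumin arrays and 1 of 3 PBS arrays held transcripts of squamous epithelium. Its camera call was lost with an estimated correlation (adjusted p = 0.140 with an estimated correlation). Among the named genes the largest fall was in Acaa1b, a peroxisomal thiolase (-1.33 ± 0.29), a call lost in 4 of the 18 fits that left out 1 array. Next came Bex2 (-1.14 ± 0.13), Acoxl (-0.93 ± 0.09), a gene related to peroxisomal acyl-CoA oxidases, Depp1 (-0.88 ± 0.15) and Pon1 (-0.87 ± 0.13), which encodes paraoxonase.

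In A/J limma called 1419 probe sets at a Benjamini-Hochberg adjusted p under 0.05, 935 higher and 484 lower after ovalbumin, which gave 582 genes higher and 215 lower. Of the called probe sets 164 rose and 4 fell at least 2-fold. Camera called 16 of 40 gene lists, and the 8 described first, from mucus and goblet cell to airway remodelling, kept their call with an estimated correlation (adjusted p from 7.45e-04 to 0.0403). Without single arrays the count of probe sets fell to 854, 802 and 806 (A/J PBS 1, 2 and 3), 860 (A/J ovalbumin 1) and 680 (A/J ovalbumin 3). A fit to the A/J PBS and ovalbumin arrays alone called 744, and a fit to the 10 arrays without squamous epithelium transcripts, which keeps 1 A/J ovalbumin and 1 C57BL/6 PBS array, called 120.

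In C57BL/6 lungs the same question gave a shorter list led by genes of the same kinds. Clca1 rose 70.4-fold (log2 change 6.14 ± 0.48, n = 3 per group), from 6.48 ± 0.23 to 12.62 ± 0.06 (mean ± SD), and Chil4 rose at least 55.5-fold (5.79 ± 0.40) from values near the 25th percentile. Slc26a4 rose by 3.91 ± 0.21, Muc5ac by 2.89 ± 0.24, Agr2 by 3.29 ± 0.29 and Fcgbp, a mucus-associated protein, by 2.85 ± 0.17. Ccl11 rose 5.04-fold (2.33 ± 0.22). Genes that fell included Gria1, a glutamate receptor subunit (-0.74 ± 0.13), and Dkk3 (-0.65 ± 0.11), and Lrmda (-1.20 ± 0.16). Lrmda changed by 0.27 in A/J, and its difference between the strains passed the interaction test. In such genes a difference of substrain in the C57BL/6 PBS group, weighed further below, cannot be told apart from a response to ovalbumin.

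Of the mucus and goblet cell list 11 of 19 genes rose in C57BL/6 (15 adjusted over the list alone), and of the alternatively activated macrophage list 13 of 18 (18 adjusted over the list alone), with Rnase2a at 3.84 ± 0.38 and Retnla at 2.72 ± 0.13. Cell cycle genes rose in 29 of 39 cases (37 adjusted over the list alone), including Top2a (1.75 ± 0.16) and the proliferation antigen Mki67 (1.53 ± 0.13). Of the chemokines 9 of 20 rose (10 adjusted over the list alone), such as Ccl8 (2.41 ± 0.28) and Ccl24 (1.89 ± 0.15). The macrophage and monocyte list had 6 of 22 genes higher (13 adjusted over the list alone), among them Mmp12 (2.01 ± 0.29) and the complement component C1qc (0.76 ± 0.13). The airway remodelling list had 4 of 18 higher (5 adjusted over the list alone), led by Timp1 (2.56 ± 0.15), and the dendritic cell list 3 of 17 (7 adjusted over the list alone), led by Ccl17 (2.08 ± 0.23) and the transcription factor Batf3 (1.27 ± 0.11). Of the lipid mediator genes 2 of 17 rose (3 adjusted over the list alone), the leukotriene receptor Cysltr1 (0.56 ± 0.12) and the phospholipase Pla2g4a (0.40 ± 0.08), whose calls were lost in 5 and 3 of the 18 fits that left out 1 array. Of 11 eosinophil genes 1 rose, and camera did not call that list (adjusted p = 0.133). The type I interferon-stimulated list had 2 of 34 genes higher (12 adjusted over the list alone), among them the antiviral gene Oas1a (0.75 ± 0.12), and its camera call was lost with an estimated correlation (adjusted p = 0.133 with an estimated correlation). The log2 changes of Il13 (0.22 ± 0.11), Il4 (0.30 ± 0.11), Il5 (0.21 ± 0.09), Ifng (0.10 ± 0.28) and Tlr7 (0.20 ± 0.10) did not pass the test in C57BL/6, while Cxcl10 rose (1.68 ± 0.27). Skeletal muscle genes had a median change of -1.61 without a call for any member, in a comparison where 1 of 3 ovalbumin arrays and 2 of 3 PBS arrays held squamous epithelium transcripts.

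Limma called 478 probe sets in C57BL/6 (Benjamini-Hochberg), 394 higher and 84 lower, or 262 genes higher and 28 lower, and 98 probe sets rose and 9 fell at least 2-fold. Camera called 20 of 40 lists, and 8 kept their call with an estimated correlation (adjusted p from 8.75e-04 to 0.0479), which are the mucus, alternatively activated macrophage, cell cycle, chemokine, macrophage, remodelling, dendritic cell and lipid mediator lists. Without single arrays the count fell to 298 (C57BL/6 PBS 1), 260 and 307 (C57BL/6 ovalbumin 2, which had the highest control 3' to 5' differences, and 3). A fit to the C57BL/6 PBS and ovalbumin arrays alone called 273, and a fit to the 10 arrays without squamous epithelium transcripts called 141.

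The ovalbumin effects of the strains shared genes. Of the 582 genes higher in A/J and the 262 higher in C57BL/6, 217 were called higher in both strains, such as Clca1, Chil4, Slc26a4 and Agr2, against 8.38 expected for independent lists of these sizes. Of the 215 and 28 genes lower in each strain, 17 were called lower in both, among them Gria1 (-0.80 ± 0.13 in A/J and -0.74 ± 0.13 in C57BL/6), against 0.331 expected. Of the 582 genes higher in A/J, 558 had a change above 0 in C57BL/6, with a median of 0.38 there and 0.59 in A/J. No array enters the differences of both strains, but all 18 arrays share 1 estimate of the spread per probe set. The expected counts do not allow for that. Without C57BL/6 ovalbumin 2 the overlap of higher genes was 135. That of lower genes was 9 and 8 without A/J PBS 2 and 3, 11 and 10 without A/J ovalbumin 1 and 3, 7, 7 and 8 without C57BL/6 PBS 1, 2 and 3, and 8, 5 and 9 without C57BL/6 ovalbumin 1, 2 and 3. In the 10 arrays without squamous epithelium transcripts the overlap of higher genes was 50. Limma called 0 genes lower in both strains there, and 72 were lower in both at an unadjusted p under 0.05.

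**Figure D1:**
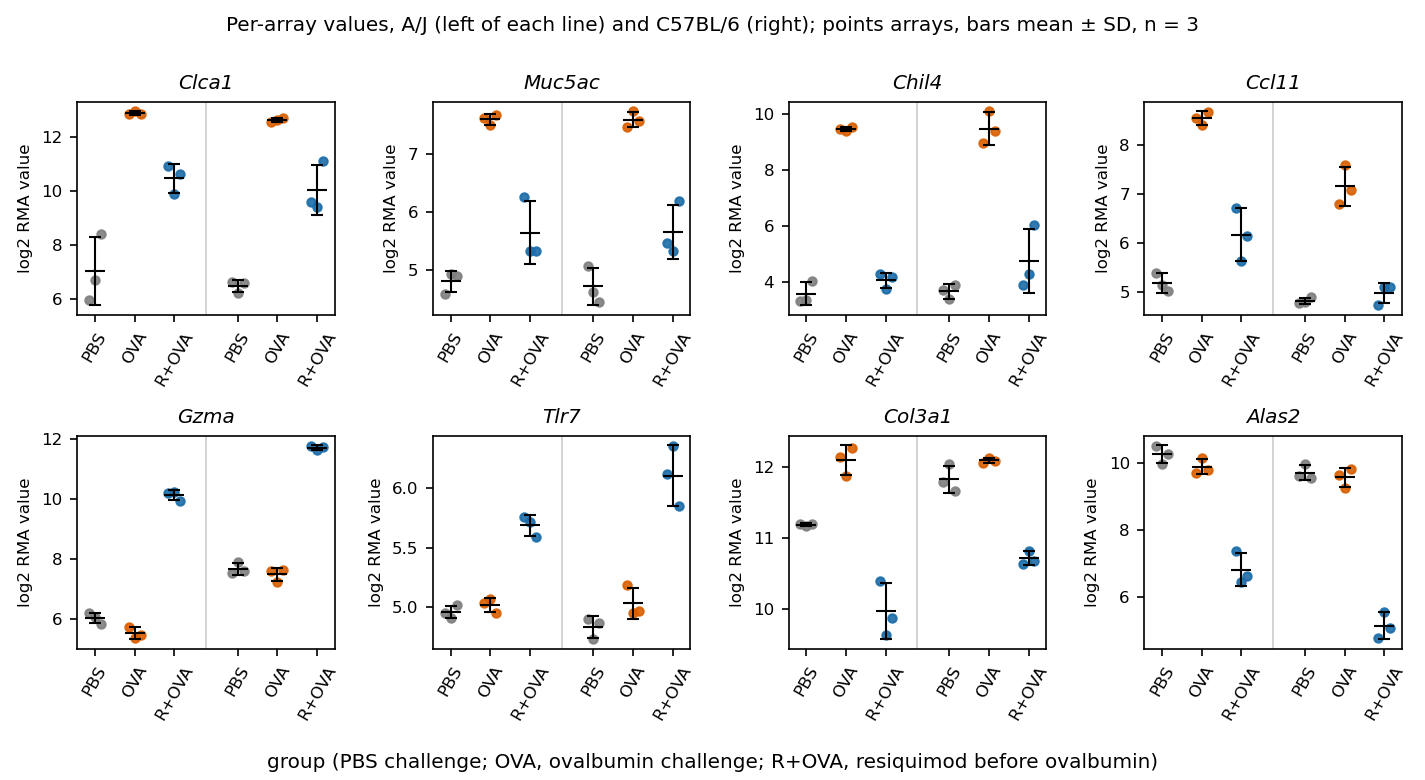
Log2 values of 8 genes (vertical axes) in the 6 groups (horizontal axes), A/J left and C57BL/6 right of each grey line, where points are single arrays and black bars are mean ± SD of 3 arrays. Clca1, Muc5ac, Chil4 and Ccl11 were higher after ovalbumin (OVA) and lower again with resiquimod (R+OVA), where Gzma and Tlr7 were higher and Col3a1 and Alas2 lower than after ovalbumin alone.

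The next comparison asked which transcripts differ in ovalbumin-challenged A/J mice that had received resiquimod. Resiquimod lowered genes of the alternatively activated macrophage and mucus lists in A/J lungs and raised genes of cytotoxic lymphocytes. Chil4 fell at least 41.8-fold (log2 change -5.39 ± 0.40, n = 3 per group), from 9.46 ± 0.08 to 4.07 ± 0.28 (mean ± SD), and Rnase2a fell 29.3-fold (-4.87 ± 0.38). Ccl11 fell by -2.38 ± 0.22, Muc5ac by -1.96 ± 0.24 and Clca1 by -2.42 ± 0.48. Gzma (Entrez Gene 14938), a granzyme of cytotoxic T and NK cells, rose 24.1-fold (4.59 ± 0.13), Gzmb rose 11.5-fold (3.52 ± 0.18) and Prf1, the pore-forming perforin, rose 9.44-fold (3.24 ± 0.20). Tlr7, the receptor that resiquimod activates, rose 1.59-fold (0.67 ± 0.10).

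Of the alternatively activated macrophage list 15 of 18 genes fell in A/J (16 adjusted over the list alone), including Cd209e (-3.56 ± 0.21) and the lectin Mgl2 (-3.22 ± 0.15). Of the mucus and goblet cell list 12 of 19 fell (14 adjusted over the list alone), including Slc26a4 (-3.01 ± 0.21) and Itln1 (-2.85 ± 0.20). The type 2 cytokine and receptor list had 3 of 18 genes lower (4 adjusted over the list alone), Il33 (-1.47 ± 0.18), the eotaxin receptor Ccr3 (-0.54 ± 0.10) and Il4 (-0.49 ± 0.11), and the Il4 call was lost in 2 of the 18 fits that left out 1 array. Il13 (-0.18 ± 0.11) and Il5 (-0.23 ± 0.09) did not pass the test. Of the NK and cytotoxic list 14 of 19 genes rose (16 adjusted over the list alone), among them Nkg7 (2.95 ± 0.15), a granule protein, Klrd1 (2.68 ± 0.16), an NK receptor chain, and the chemokine Ccl5 (2.95 ± 0.15). The macrophage and monocyte list had 13 genes higher and 2 lower of 22 (14 and 3 adjusted over the list alone), with the Fc receptor Fcgr4 (2.59 ± 0.14) and the scavenger receptor Marco (1.97 ± 0.24) higher and Mmp12 (-2.28 ± 0.29) lower. Of the dendritic cell list 9 of 17 fell (11 lower and 1 higher adjusted over the list alone), such as the lectin Cd209a (-3.05 ± 0.21) and Ccl17 (-2.30 ± 0.23).

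Structural genes fell as well, in a comparison where the 3' to 5' difference of the beta-actin control, a sign of RNA quality, also separated the groups (0.48 against 0.38, exact permutation p = 0.1). A smaller share of structural cells in the lung was not told apart from lower expression in these cells. The fibroblast and matrix list had 10 genes lower and 1 higher of 18 in A/J (13 and 1 adjusted over the list alone), led by the fibrillar collagens Col3a1 (-2.13 ± 0.15) and Col1a1 (-1.98 ± 0.15). Of the smooth muscle list 9 of 14 fell (10 adjusted over the list alone), among them Actg2 (-1.28 ± 0.13) and Tagln (-0.71 ± 0.08), while 2 of 3 ovalbumin arrays and 1 of 3 resiquimod arrays held squamous epithelium transcripts. Of the red cell list 5 of 8 fell (5 adjusted over the list alone), led by Alas2, the erythroid enzyme that starts haem synthesis (-3.08 ± 0.24). Of the neutrophil list 10 rose and 1 fell of 18 (12 and 2 adjusted over the list alone), including the calcium-binding S100a8 (2.39 ± 0.38) and S100a9 (2.26 ± 0.40), with adjusted p = 0.118 with an estimated correlation. Of the MHC class II list 7 of 13 fell (8 adjusted over the list alone), among them H2-Eb1 (-0.76 ± 0.12) and H2-Aa (-0.68 ± 0.12), with adjusted p = 0.149 with an estimated correlation. Of the MHC class I processing list 7 of 12 rose (8 adjusted over the list alone), including H2-K1 (0.68 ± 0.07) and the immunoproteasome subunit Psmb8 (0.65 ± 0.11), with adjusted p = 0.181 with an estimated correlation. Cxcl10 fell (-1.17 ± 0.27), a call lost in 2 of the 18 fits that left out 1 array, and Ifng (0.50 ± 0.28) did not pass the test.

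In A/J limma called 3206 probe sets for resiquimod (Benjamini-Hochberg), 1519 higher and 1687 lower, or 796 genes higher and 981 lower, and 157 probe sets rose and 170 fell at least 2-fold. Camera called 23 of 40 lists, and 9 kept their call with an estimated correlation (adjusted p from 0.00852 to 0.0479), which are the alternatively activated macrophage, mucus, type 2 cytokine, NK, macrophage, dendritic cell, fibroblast, smooth muscle and red cell lists. A fit to the A/J ovalbumin and resiquimod arrays alone called 1092 probe sets, and a fit to the 10 arrays without squamous epithelium transcripts called 574. Without the 3 A/J arrays that held liver or stomach transcripts, which leaves 1 A/J resiquimod array that is assumed to vary like the other groups, the count was 1757.

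In C57BL/6 mice resiquimod raised genes of cytotoxic lymphocytes, MHC class I processing and the cell cycle, and lowered genes of the alternatively activated macrophage and mucus lists. Gzmb rose 19.8-fold (log2 change 4.31 ± 0.18, n = 3 per group) and Gzma rose 18.6-fold (4.22 ± 0.13), from 7.48 ± 0.22 to 11.70 ± 0.07 (mean ± SD). Klra7 and Klra8, receptors of NK cells from the Ly49 family, rose by at least 4.42 ± 0.10 and 4.29 ± 0.13, from ovalbumin group means of 2.96 ± 0.01 and 3.23 ± 0.18 (mean ± SD), among the weakest signals. Tbx21, the transcription factor of type 1 responses, rose by 2.85 ± 0.16, and Tlr7 rose 2.11-fold (1.08 ± 0.10). Chil4 fell 26.3-fold (-4.72 ± 0.40), with C57BL/6 resiquimod 3 at 6.06 against 3.92 and 4.30 in C57BL/6 resiquimod 1 and 2. In the fit without C57BL/6 resiquimod 3 Chil4 fell at least 41.3-fold. Ccl11 fell by -2.18 ± 0.22, Muc5ac by -1.94 ± 0.24 and Clca1 by -2.59 ± 0.48.

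Of the NK and cytotoxic list 18 of 19 genes rose in C57BL/6 (18 adjusted over the list alone), among them Prf1 (3.63 ± 0.20), Ccl5 (3.46 ± 0.15) and Nkg7 (3.31 ± 0.15). Of the MHC class I processing list 11 of 12 rose (11 adjusted over the list alone), such as the peptide transporter Tap1 (1.09 ± 0.18) and Psmb9 (0.96 ± 0.10). The cell cycle list had 31 of 39 genes higher (37 adjusted over the list alone), led by Birc5 (1.21 ± 0.20) and Racgap1 (1.20 ± 0.14). The macrophage and monocyte list had 15 higher and 1 lower of 22 (18 and 1 adjusted over the list alone), with Fcgr4 (3.50 ± 0.14) and the integrin Itgam (2.01 ± 0.28) among the higher. Of the alternatively activated macrophage list 13 of 18 fell (16 adjusted over the list alone), including Mgl2 (-3.62 ± 0.15) and Ccl17 (-2.69 ± 0.23). Of the mucus and goblet cell list 11 of 19 (13 adjusted over the list alone), including Slc26a4 (-3.34 ± 0.21) and Agr2 (-2.36 ± 0.29). Of the smooth muscle list 10 of 14 fell (12 adjusted over the list alone), such as Actg2 (-1.18 ± 0.13) and its transcriptional activator Myocd (-0.98 ± 0.12), with squamous epithelium transcripts in 1 of 3 arrays of each group. Of the fibroblast and matrix list 8 of 18 fell (11 adjusted over the list alone), such as Col3a1 (-1.38 ± 0.15), Col1a1 (-1.22 ± 0.15) and elastin, Eln (-0.87 ± 0.15). Of the red cell list 4 of 8 fell (5 adjusted over the list alone), led by Alas2 (-4.45 ± 0.24).

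Several lists moved in C57BL/6 without keeping their camera call once the correlation was estimated. B cell genes rose in 11 of 17 cases (13 adjusted over the list alone), among them Ms4a1, the CD20 antigen (1.98 ± 0.35), and the B cell receptor chains Cd79b (1.57 ± 0.29) and Cd79a (1.53 ± 0.27), with adjusted p = 0.134 with an estimated correlation. The interferon-gamma and type 1 list had 11 higher and 1 lower of 28 (13 and 1 adjusted over the list alone), such as Stat4 (1.48 ± 0.14) and the chemokine Cxcl9 (1.52 ± 0.17), with adjusted p = 0.0578 with an estimated correlation. Ifng (0.92 ± 0.28) and Cxcl10 (0.15 ± 0.27) did not pass the test, nor did Il13 (-0.20 ± 0.11), Il4 (-0.15 ± 0.11) and Il5 (-0.22 ± 0.09). T cell genes rose in 6 of 20 cases (6 adjusted over the list alone), including Cd2 (1.28 ± 0.13) and Thy1 (1.05 ± 0.13), with adjusted p = 0.272 with an estimated correlation. Neutrophil genes rose in 9 and fell in 1 of 18 cases (12 and 1 adjusted over the list alone), such as the granule protein Ngp (2.17 ± 0.31), with adjusted p = 0.134 with an estimated correlation. The alveolar type 1 and alveolar type 2 cell lists had 6 of 12 and 6 of 14 genes lower (8 and 7 adjusted over the list alone), among them the tight junction gene Cldn18 (-0.52 ± 0.08) and the lipogenic enzyme Scd1 (-0.99 ± 0.12). Their adjusted p were 0.134 and 0.122 with an estimated correlation.

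In C57BL/6 limma called 3520 probe sets for resiquimod (Benjamini-Hochberg), 2081 higher and 1439 lower, or 1055 genes higher and 836 lower, and 282 probe sets rose and 99 fell at least 2-fold. Camera called 30 of 40 lists, and 9 kept their call with an estimated correlation (adjusted p from 0.00314 to 0.0408), which are the 9 lists described before the B cells. Without C57BL/6 resiquimod 3 the count was 2259, and a fit to the 10 arrays without squamous epithelium transcripts called 1398. Between the strains 343 genes were called higher in both after resiquimod, such as Gzma, Gzmb, Prf1 and Nkg7, against 46.2 expected for independent lists. Another 392 genes were called lower in both, such as Chil4, Alas2 and Col3a1, against 45.1 expected. In the 10 arrays without squamous epithelium transcripts these overlaps were 74 and 128. In the opposite direction to A/J, 2 genes called higher and 10 called lower in A/J were called in C57BL/6.

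**Figure D2:**
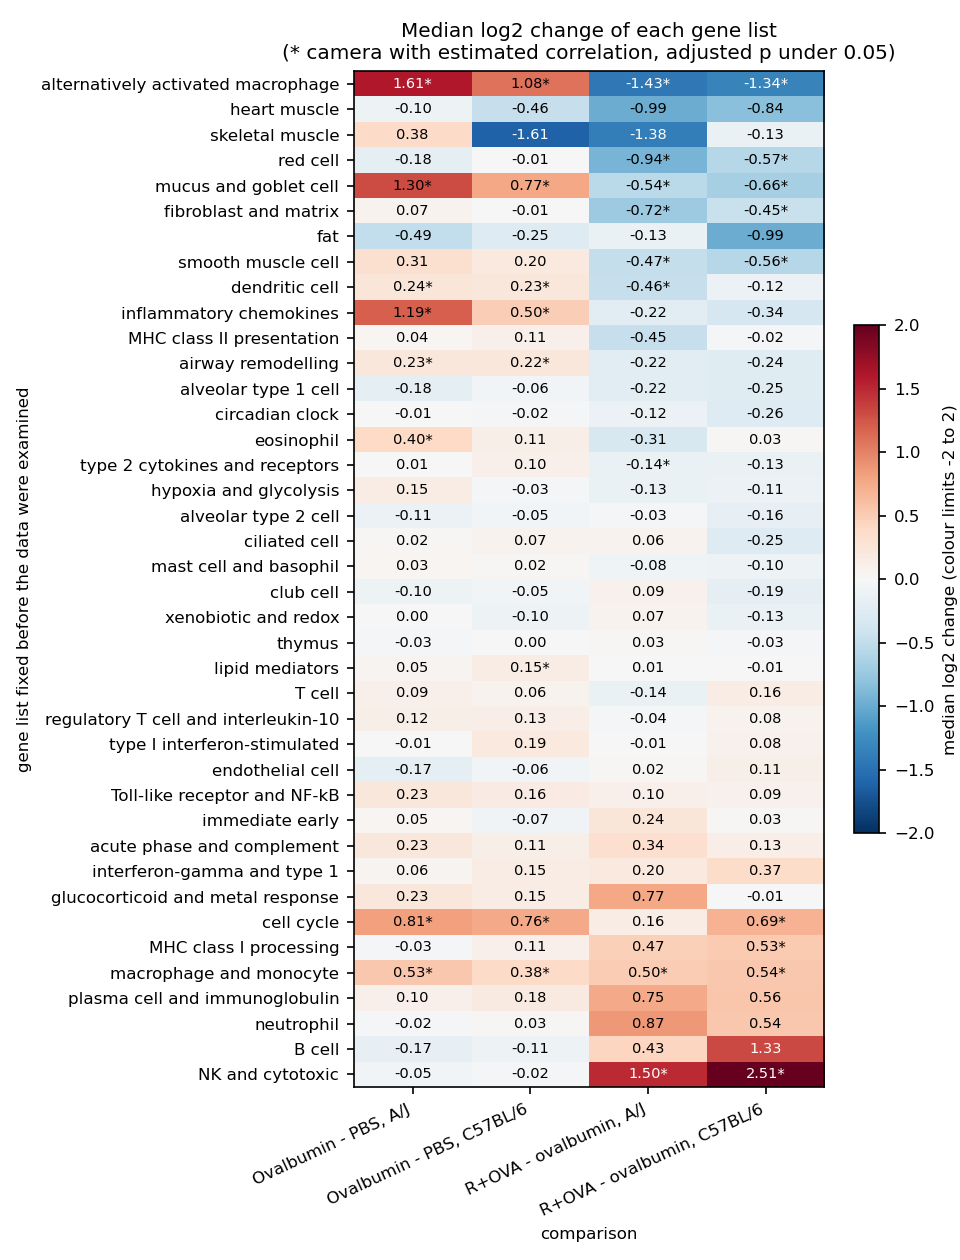
Median log2 change (colour and printed value) of the measured members of each of the 40 gene lists (vertical axis) in the 4 main comparisons (horizontal axis), with n = 3 arrays per group, where an asterisk stands for an adjusted p under 0.05 by camera with an estimated correlation. The alternatively activated macrophage list had medians of 1.61 and 1.08 after ovalbumin and of -1.43 and -1.34 after resiquimod, and the NK and cytotoxic list had medians of 1.50 and 2.51 after resiquimod.

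The next comparison asked how far the genes raised by ovalbumin were lowered by resiquimod. So that no array entered both differences, genes called in 1 strain were followed in the other. The calls still share the spread estimated from all 18 arrays, so a gene with little spread is called more readily in both. The shares among genes not called, given for comparison, are therefore no matched baseline. Of the 582 genes raised by ovalbumin in A/J, 145 (24.9%) were called lower after resiquimod in C57BL/6, among them Chil4, Clca1, Slc26a4, Muc5ac and Ccl11, and 136 were called higher, among them Saa3, an acute phase protein (1.63 ± 0.22), and Cxcl9. The median change of the 582 genes after resiquimod in C57BL/6 was -0.02, with 300 of them below 0. Among the 17396 genes not called for ovalbumin in A/J, 3.83% were called lower and 5.23% higher. Of the 262 genes raised in C57BL/6, 98 (37.4%) were called lower after resiquimod in A/J and 16 were called higher, again with Saa3 (2.32 ± 0.22), against 4.91% and 4.31% among the 17903 genes not called. The 262 genes had a median change of -0.17 after resiquimod in A/J, with 174 of them below 0. Of the 215 genes lowered by ovalbumin in A/J, 9 (4.19%) were called higher after resiquimod in C57BL/6 and 24 lower. Of the 28 genes lowered in C57BL/6, 9 (32.1%) were called higher after resiquimod in A/J and 4 lower. Within a strain the comparisons share the ovalbumin arrays, and 215 of 582 genes in A/J and 81 of 262 in C57BL/6 were called lower, where simulated resiquimod groups drawn like the ovalbumin group gave 0.0624% and 0.0433% on average over 50 simulations, and at most 56 and 41 genes in 1 simulation. Groups drawn like the PBS group gave 72.5% and 67.6%. The simulated lists were longer than the real ones, with 1373 and 930 genes on average. In C57BL/6, 82 of the 262 genes were called higher within the strain, for example cell cycle genes such as Birc5 and the chemokine Cxcl9.

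Leaving out A/J ovalbumin 3 lowered the count within A/J from 215 to 131, and leaving out the 3 arrays with liver or stomach transcripts lowered it to 137. In the 10 arrays without squamous epithelium transcripts the counts were 44 and 33 across strains (genes called in A/J and in C57BL/6) and 46 and 37 within A/J and within C57BL/6.

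**Figure D3:**
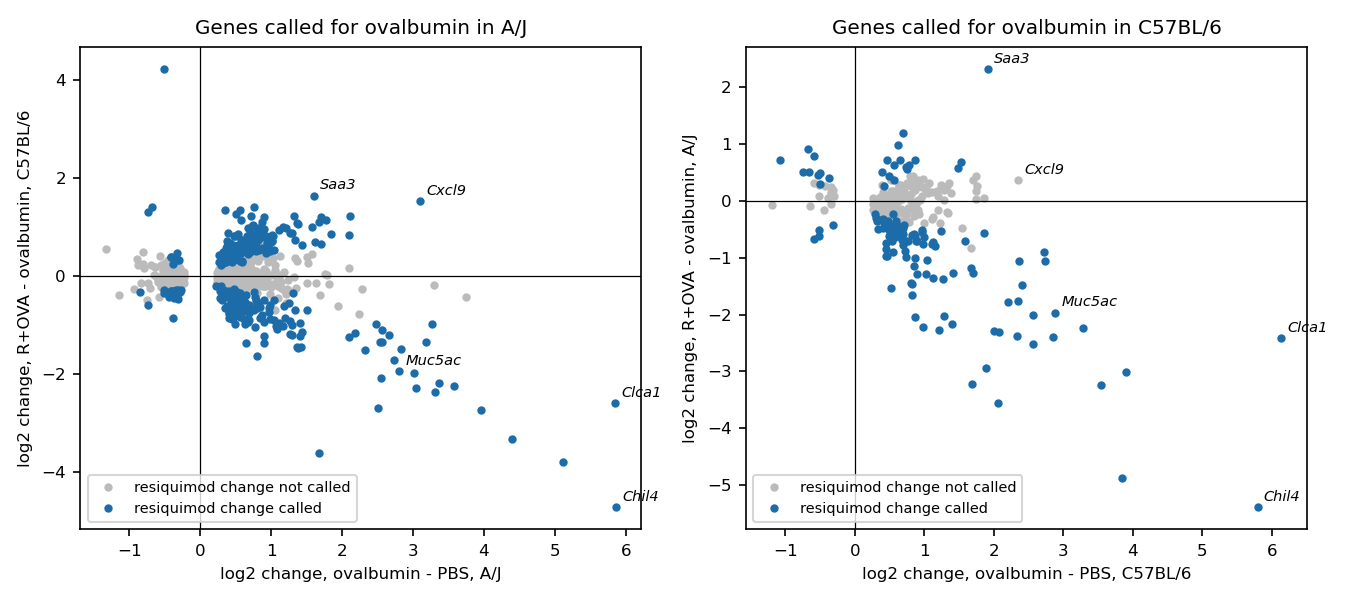
Log2 change after ovalbumin in 1 strain (horizontal axes) against log2 change after resiquimod in the other strain (vertical axes), where each point is a gene called for ovalbumin in the strain of the horizontal axis and blue points were also called for resiquimod. Left are the 582 genes raised and 215 lowered in A/J and right the 262 raised and 28 lowered in C57BL/6. Chil4 and Clca1 lie far right and low in both panels.

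Resiquimod-treated mice were also compared with the PBS groups. In A/J, Gzma was higher than in the PBS group (log2 change 4.08 ± 0.13, n = 3 per group), and the acute phase gene Saa3 15.1-fold higher (3.92 ± 0.22), while Alas2 was lower (-3.45 ± 0.24), as was Fmod, a collagen-binding proteoglycan (-2.54 ± 0.44). Muc5ac and Ccl11, chosen for this comparison after their values were seen, stayed higher than in the PBS group (0.84 ± 0.24 and 0.99 ± 0.22). Muc5ac lay at 6.27 in A/J resiquimod 1, the array with stomach transcripts. It lay at 5.34 and 5.32 in A/J resiquimod 2 and 3, and between 4.59 and 4.93 in the A/J PBS arrays. In C57BL/6, Klra7 (at least 4.37 ± 0.10, from PBS values among the weakest signals), Gzmb (4.22 ± 0.18) and Cxcl9 (3.87 ± 0.17) were higher and Alas2 (-4.59 ± 0.24) and Thrsp, a lipogenic gene (-4.19 ± 0.70), lower. Of the fat list 1 of 11 genes was lower in this comparison (4 adjusted over the list alone), with adjusted p = 0.455 with an estimated correlation, and its list mean differed by -1.19 without overlap between the 3 arrays of each group. Muc5ac was higher (0.95 ± 0.24), while Ccl11 (0.15 ± 0.22) did not pass the test. Of the mucus and goblet cell list 9 of 19 genes were higher than PBS in A/J (12 adjusted over the list alone) and 6 in C57BL/6 (8 adjusted over the list alone, adjusted p = 0.284 with an estimated correlation in C57BL/6). Stomach transcripts were present in 1 of 3 A/J resiquimod arrays and in no other array of these groups. Cell cycle genes were higher in 30 and 38 of 39 cases in A/J and C57BL/6 (37 and 39 adjusted over the list alone). Of the chemokine list 12 were higher and 1 lower of 20 in A/J (13 and 2 adjusted over the list alone).

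Limma called 3636 probe sets in A/J, 1845 higher and 1791 lower, and 5589 in C57BL/6, 3195 higher and 2394 lower (Benjamini-Hochberg). The A/J count was 2373 without A/J PBS 3, 2172 in a fit to the compared groups alone, 2158 without the arrays with liver or stomach transcripts and 1492 in the 10 arrays without squamous epithelium transcripts, where the C57BL/6 count was 1362.

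Between the PBS groups, A/J lungs held more Gbp2b transcript, an interferon-inducible guanylate-binding protein, by a log2 difference of 4.95 ± 0.21 (n = 3 per group), and more Pik3ap1, an adaptor of phosphoinositide 3-kinase signalling (3.27 ± 0.18), than C57BL/6 lungs. The ribonuclease gene Ang (-5.88 ± 0.22) and the transcription factor gene Sox11 (-4.98 ± 0.17) were lower in A/J. Of the NK and cytotoxic list 6 of 19 genes were lower in A/J (9 adjusted over the list alone), with adjusted p = 0.979 with an estimated correlation. The mitochondrial transhydrogenase gene Nnt was higher in A/J (1.40 ± 0.09), as was Wdfy1 (1.30 ± 0.09), both chosen after their values were seen, and both were also higher in the other C57BL/6 groups than in the C57BL/6 PBS group. Limma called 3845 probe sets, 1850 higher and 1995 lower in A/J (Benjamini-Hochberg). A probe can bind the transcript of a strain less well where its sequence differs, and the files do not show which probe sets this touches. The 10 arrays without squamous epithelium transcripts gave 1442 calls.

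Differences between the strains in their response were tested as interactions. For ovalbumin, Itln1 had a larger change in A/J (3.76 ± 0.20) than in C57BL/6 (0.77 ± 0.20, not past the test), with a difference of 2.98 ± 0.29 (n = 3 per group in 4 groups). Guca2a, the guanylin precursor (difference 1.84 ± 0.21), and Wfdc17, a protease inhibitor-like gene of macrophages (1.43 ± 0.16), also changed more in A/J, and Nnt (-1.38 ± 0.13) and Wdfy1 (-1.13 ± 0.13) less. The differences of Nnt and Wdfy1 rest on their low values in the C57BL/6 PBS group. A difference of substrain in that group, weighed further below, cannot be told apart from a response to ovalbumin. For resiquimod, Klra7 and Klra8 had log2 changes of 0.11 ± 0.10 and 0.09 ± 0.13 in A/J, which did not pass the test there, and differences of -4.30 ± 0.14 and -4.20 ± 0.19. The rises in C57BL/6, which began among the weakest signals, are lower bounds. In A/J the ovalbumin and resiquimod group means of these genes lay among the weakest signals as well (2.48 to 2.65). A change could be missed there, so the differences between the strains are not bounded in size. As background, the Ly49 gene family varies in gene content between inbred strains. Itln1 (-2.41 ± 0.29) and Guca2a (-2.06 ± 0.21) had more negative changes in A/J, and Lox, a collagen cross-linking enzyme (1.91 ± 0.22), and the glucocorticoid-induced transcription factor gene Klf15 (1.31 ± 0.26) more positive ones. The ovalbumin arrays enter both interactions with opposite signs, so the ovalbumin and resiquimod differences of Itln1 and of Guca2a are not independent. The Klf15 call was lost in 5 of the 18 fits that left out 1 array. Of the cell cycle list 8 of 39 genes had lower changes in A/J (21 adjusted over the list alone), such as Uhrf1 (-1.18 ± 0.18) and Mcm3 (-0.88 ± 0.14), both chosen after their values were seen, with adjusted p = 0.206 with an estimated correlation, and of the NK and cytotoxic list 5 of 19 (11 adjusted over the list alone), with adjusted p = 0.206 with an estimated correlation.

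Limma called 21 probe sets for the difference in the ovalbumin effect (14 more positive in A/J) and 378 for the difference in the resiquimod effect (119 more positive in A/J), with Benjamini-Hochberg adjustment. Camera called 11 and 17 lists, and with an estimated correlation it called 0 and 0 (5 and 7 lists at an unadjusted p under 0.05), where fry called 0 and 8 (6 and 17 unadjusted). The resiquimod count was 163 and 151 without A/J ovalbumin 1 and 3, 636 and 154 without A/J resiquimod 1 and 3, 234, 178 and 213 without C57BL/6 ovalbumin 1, 2 and 3, and 180, 250 and 138 without C57BL/6 resiquimod 1, 2 and 3. The counts for ovalbumin and resiquimod were 36 and 730 with an intensity trend and robust moderation and 3 and 6 in the 10 arrays without squamous epithelium transcripts. The ovalbumin count was 91 with the first component within groups as a covariate, and the resiquimod count 608 with the low-signal filter, 87 in a fit to the compared groups alone and 135 without the arrays with liver or stomach transcripts.

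Some samples held transcripts that normal lung does not make in quantity. In 8 of 18 arrays Krt4 and Krt13, keratins of squamous mucosa such as that of the oesophagus, lay between 10.5 and 12.3 and between 10.7 and 11.9 on the log2 scale, against 3.82 to 5.48 and 3.21 to 4.30 in the other 10. These arrays were A/J PBS 1, A/J ovalbumin 1 and 3, A/J resiquimod 1, C57BL/6 PBS 1 and 3, C57BL/6 ovalbumin 1 and C57BL/6 resiquimod 2. Alb, the liver's serum albumin, lay between 10.1 and 11.3 in A/J ovalbumin 1 and A/J resiquimod 3 and between 3.15 and 4.51 elsewhere. The stomach gene Gkn2 lay at 10.7 in A/J resiquimod 1 and between 4.14 and 4.71 elsewhere. Among the lists for handling and other tissues fixed beforehand, some list means separated the 3 arrays of each group fully, which gives an exact permutation p of 0.1 (two-sided), the smallest that 3 against 3 arrays allow, as chance gives in 1 of 10 splits. Between resiquimod and ovalbumin groups these were the red cell list mean, with differences of -0.87 in A/J and -1.12 in C57BL/6, and the circadian clock list mean, with differences of -0.16 and -0.24. Between ovalbumin and PBS groups they were the immediate early list mean in A/J (0.23) and the heart muscle list mean in C57BL/6 (-0.50). Between resiquimod and PBS groups they were the red cell (-1.07) and immediate early (0.35) list means in A/J, and the red cell (-1.11), circadian clock (-0.24), heart muscle (-1.39), fat (-1.19) and thymus (0.07) list means in C57BL/6. Between the PBS groups it was the red cell list mean (0.30). The difference between 3' and 5' probe sets of the Gapdh control, a sign of RNA degradation, gave exact permutation p from 0.5 to 1 in the 7 comparisons of 2 groups (two-sided). That of beta-actin gave an exact permutation p of 0.1 for resiquimod against ovalbumin in A/J, with a mean of 0.48 against 0.38, and from 0.2 to 0.6 in the others. A single array stood apart in both, C57BL/6 ovalbumin 2, with 0.56 for Gapdh (-0.06 to 0.10 in the other 17 arrays) and 0.67 for beta-actin (0.34 to 0.57). Without it the ovalbumin count in C57BL/6 was 260.

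**Figure D4:**
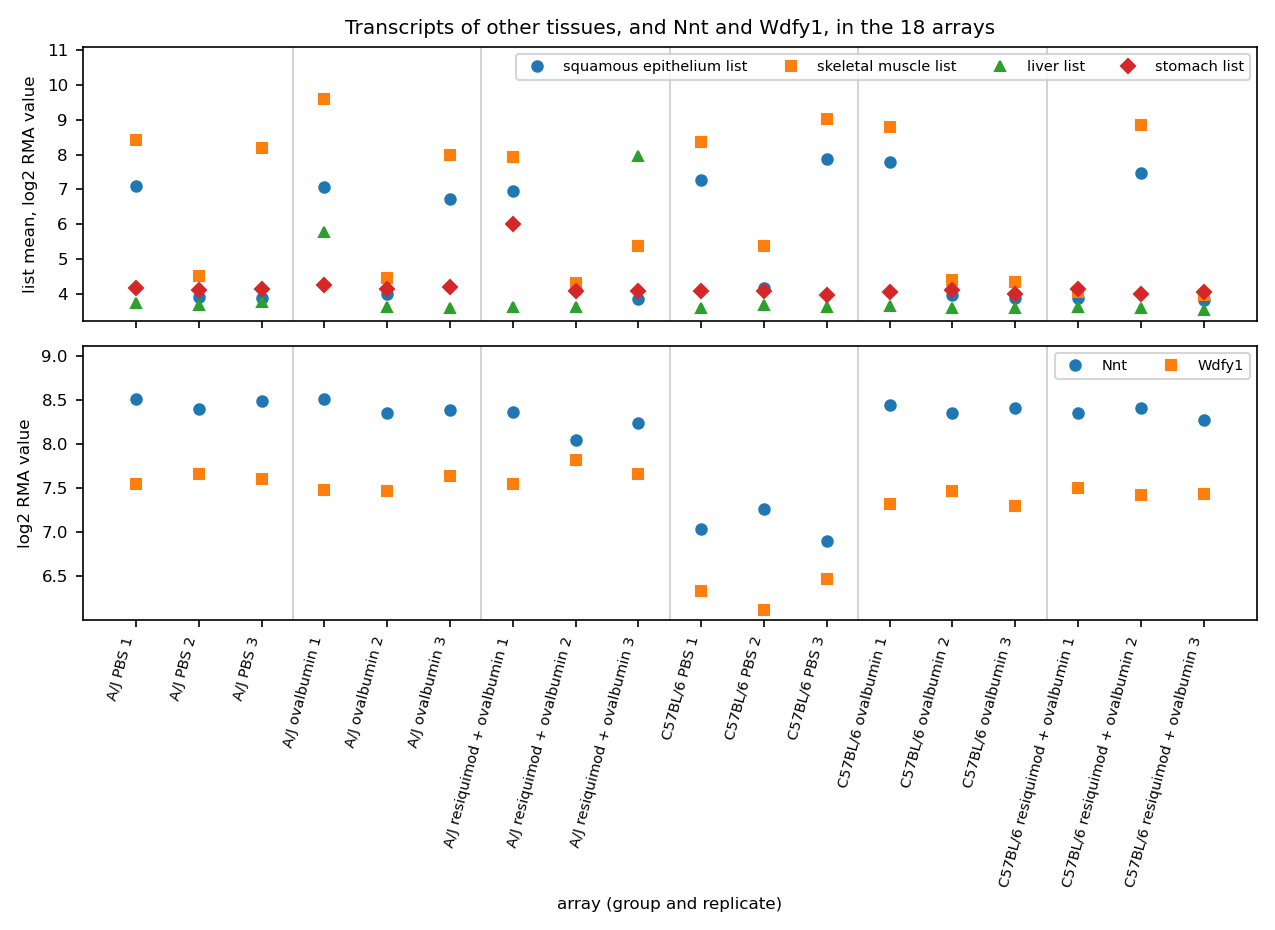
Mean log2 value of the squamous epithelium, skeletal muscle, liver and stomach lists (upper panel) and log2 values of Nnt and Wdfy1 (lower panel) on the vertical axes, for the 18 arrays in group order on the horizontal axis, 1 point per array and gene or list. The squamous list lies between 6.71 and 7.88 in 8 arrays and between 3.82 and 4.17 in the others, and Nnt and Wdfy1 are lowest in the 3 C57BL/6 PBS arrays.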

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

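The tests of tissue from outside the lung as the source of squamous transcripts, of a lung response to treatment, of the platelet list and of Nnt and Wdfy1 were chosen only after the result was seen. The squamous-tissue block was also chosen after these transcripts were seen, though its test was written down before it was run. The interaction tests and the splits of the arrays were planned. No group had more than 3 arrays, so single arrays were not tested as outliers. The results listed next were singled out because the difference between the strains in an effect passed limma's interaction test (Benjamini-Hochberg adjusted p from 1.33e-04 to 0.0422 for ovalbumin and from 4.40e-11 to 0.0439 for resiquimod, 9 and 25 named genes).

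For the ovalbumin effect, the A/J minus C57BL/6 differences (log2, n = 3 per group) were 2.98 for Itln1, 1.84 for Guca2a, 1.50 for Fxyd4, 1.46 for Lrmda, 1.43 for Wfdc17, 0.87 for Ccl22, -0.93 for Efcab7, -1.13 for Wdfy1 and -1.38 for Nnt. In 6 of these 9 genes the change was more positive in A/J, and the calls of Ccl22, Fxyd4 and Lrmda were lost in 15, 14 and 4 of the 18 fits that left out 1 array. All of these differences use the C57BL/6 PBS group, where a difference of substrain cannot be excluded.

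For the resiquimod effect, immune genes with a lower change in A/J were Klra7 (-4.30), Klra8 (-4.20), Itln1 (-2.41), Siglecf (-1.49), Fcer2a (-1.23), Cxcl9 (-1.16), Cd8b1 (-1.14), Cd2 (-1.08), Prg2 (-0.98), Fcgr4 (-0.90) and Epsti1 (-0.71). For Klra7 and Klra8 the C57BL/6 rise began among the weakest signals and is a lower bound. Their A/J values lay among the weakest signals too, where a change could be missed, so these 2 differences are not bounded in size. The replication genes Uhrf1 (-1.18) and Mcm3 (-0.88), the endothelial genes Emcn (-1.26) and Sox17 (-0.80), Guca2a (-2.06) and the transporter gene Slc13a3 (-1.71) also had lower changes in A/J. Itln1 and Guca2a are listed for ovalbumin too, and both effects use the ovalbumin arrays, so these listings are not independent. Higher changes in A/J were found for A2ml1 (2.06), Lox (1.91), Galnt15 (1.79), Ankrd63 (1.76), the transcription factor gene Klf15 (1.31), the clock gene Nr1d1 (0.75), Selenbp1 (0.68) and the ciliary gene Ak7 (0.64). In the 18 fits that left out 1 array, 14 of these 25 genes kept their call in every fit. The calls of the other 11 were lost in 15 fits for Nr1d1, 14 for Prg2, 13 each for Fcgr4 and Sox17, 11 each for Epsti1 and Selenbp1, 10 for Cxcl9, 5 each for Klf15 and Ak7, 4 for Cd8b1 and 3 for Siglecf.

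For the interactions, treatment labels were shuffled within each strain. For ovalbumin 5 of 100 shuffles, the real one included, gave at least the 21 real calls, with 2502 as the highest other. For resiquimod 10 of 100 gave at least the 378 real calls, with 5737 as the highest other. By these shares chance cannot be excluded for either count. However, a shuffle that moves the labels of the strains in opposite directions carries the treatment effects into the interaction, and the highest shuffles, which swap all labels of 1 strain, point to that structure of the samples. Such shuffles were 3 of the 4 and 8 of the 9 others that reached the real count, so the shares are too high as a measure of chance. Of the 46 and 45 shuffles not of that kind, a division made after the result was seen, 1 and 1 reached the real count (highest 215 and 622). Where the strains keep unlike numbers of labels, these shuffles still carry part of the treatment effects, so they do not measure chance alone either. For each comparison of 2 groups, the 10 splits of 6 arrays are too few for a share under 0.05, and 1 split, the real one, gave as many calls. The real counts were 1419, 478, 3206, 3520, 3636, 5589 and 3845, in the order of the report. The highest other split gave 0 in each by limma at an adjusted p under 0.05, with at most 3119, 3063, 4438, 2969, 2820, 3126 and 2456 probe sets at an unadjusted p under 0.05. At the same unadjusted threshold the real split gave 6695, 4714, 8802, 9307, 9283, 10915 and 8525. Every other split mixes the 2 groups, so a real effect enters its residual spread and lowers its calls. Neither the 0 nor the unadjusted counts of the other splits therefore measure chance.

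Squamous epithelium transcripts in 8 of 18 arrays may come from tissue outside the lung, such as oesophagus or upper airway, as a hypothesis. The skeletal muscle list, fixed beforehand, lay on the same side of its midpoint as the squamous list in 17 of 18 arrays, with Acta1 between 11.3 and 12.1 in the 8 arrays and between 4.57 and 10.6 in the others, and A/J PBS 3, without squamous transcripts, was the exception (list mean 8.19). Of the 20 squamous genes 3 lay above the median signal in the other arrays. Against a response of the lung to treatment stand the 6 of 6 groups that held arrays of both kinds. Against the presence of squamous transcripts as the whole source of the main calls, 84.0%, 93.5%, 90.6% and 98.4% of the called probe sets were called the same way with the squamous-tissue block. The block marks only whether an array held such transcripts. It therefore does not cover liver, stomach or other tissue, the muscle transcripts of A/J PBS 3, or unequal amounts of tissue.

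The fall of red cell genes after resiquimod was weighed against less blood in the lungs. A list of 12 platelet genes had a median change of 0.33 in A/J and -0.0111 in C57BL/6, against red cell list medians of -0.94 and -0.57, and all 12 platelet genes lay above 0.5 times the red cell median in either strain. These values argue against less blood as the whole source, unless platelets rose at the same time, and 5 platelet genes were called higher in A/J. A change in young red cells, which carry Alas2, stays open as a biological explanation of the treatment and was not tested.

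Nnt and Wdfy1 were low in the 3 C57BL/6 PBS arrays, where Nnt lay at 7.07 ± 0.19 (SD) against a mean of 8.37 in the other 15 arrays, and 5 of the 8 probe sets of these genes had all 3 arrays below the other 15. Against a rise of both genes by ovalbumin in either strain stands the mean change of -0.0611 ± 0.0647 (SE) in A/J, against 1.19 ± 0.0647 in C57BL/6. C57BL/6 mice of different substrains in the PBS and challenged groups are a candidate explanation, since C57BL/6J mice carry a deletion in Nnt, as background, and the labels name no substrain. This cannot be told apart from a response lasting in both challenged C57BL/6 groups, which differed by 0.0171 ± 0.0647 (SE). A difference of substrain would add to every comparison with the C57BL/6 PBS group, which are ovalbumin and resiquimod against PBS in C57BL/6, A/J against C57BL/6 and the strain difference in the ovalbumin effect, and no value here shows by how many genes.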

How the results depend on the processing

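The fits with the squamous-tissue block, with the first component within groups, on the 10 arrays without squamous transcripts and without the 3 arrays with liver or stomach transcripts were chosen only after the result was seen. Counts and overlaps stayed within 1.5 times of their value in 23 of 23 results with the replicate block, 23 of 23 with arrays centred, 17 of 17 after quantile normalization, 9 of 9 with array weights, 9 of 9 without the _x_at and _s_at probe sets, 6 of 6 with the mean of a gene's probe sets and 23 of 23 with the squamous-tissue block. With arrays centred, the 20 differences in list means that measure handling moved by less than 1 SD. The deposited values were already quantile-normalized by RMA and had nearly equal array medians. Centring and a further quantile normalization could therefore change little, and they do not test other ways of normalizing. With the replicate block the counts were 1285, 444, 3176, 3475, 3602, 5562, 3861, 18 and 385 in the order of the report. The labels give the numbers no shared animal, batch or day, so the samples are taken to share only a number. Deviations of same-numbered arrays correlated over 0.1 in 12 of 21 pairs, the lowest at -0.585, and 7 of 18 arrays correlated best with their own number. All 3 pairs lay over 0.1 for resiquimod against PBS in A/J alone (0.502, 0.291 and 0.157), where the block gave 3602 calls against 3636. In the 12 pairs over 0.1 both arrays held or both lacked squamous transcripts. In every other pair, all with a correlation below 0, 1 of the arrays held them. These correlations therefore follow the squamous transcripts and cannot show that arrays with the same number belong together. Of the 475 calls of named genes, 454 held with the replicate block, 465 with the squamous-tissue block, 475 with the first component, 373 in fits to the compared groups alone and 259 in the 10 arrays without squamous transcripts. There, and in the A/J resiquimod group without the liver or stomach arrays, some groups keep 1 array that is assumed to vary like the others. The first component is built from the deviations around the group means, so it leaves every difference unchanged and lowers the residual spread. That all 475 calls held with it follows largely from its construction and is no check of the calls.

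Fewer arrays or probe sets enter some of the following fits, and no other cause was tested. With camera at an estimated correlation the list counts were 8, 8, 9 and 9 in the main comparisons and 0 and 0 for the strain differences (5 and 7 at an unadjusted p under 0.05), where fry gave 0 and 8. The low-signal filter gave 608 calls for the strain difference in the resiquimod effect, and trend with robust moderation gave 36 and 730 for the differences in the ovalbumin and resiquimod effect. With the first component as a covariate the difference in the ovalbumin effect had 91 calls. That component leaves each difference unchanged and only lowers the residual spread, so the added calls are no sign of a stronger result. Fits to the compared groups alone gave 744 and 273 for ovalbumin in A/J and C57BL/6, 1092 for resiquimod in A/J, 2172 for resiquimod against PBS in A/J and 87 for the difference in the resiquimod effect. Without liver or stomach arrays the counts were 1757 and 2158 for resiquimod against ovalbumin and against PBS in A/J, 135 for the difference in the resiquimod effect and 137 for the genes raised by ovalbumin and lowered by resiquimod within A/J. The 10 arrays without squamous transcripts gave 120, 141, 574, 1398, 1492, 1362, 1442, 3 and 6 calls in the order of the report. They gave overlaps of 50 and 0 genes for ovalbumin (limma, 72 lower in both at an unadjusted p under 0.05) and 74 and 128 for resiquimod, and 44, 33, 46 and 37 genes raised by ovalbumin and lowered by resiquimod. Without _x_at and _s_at probe sets another probe set stood for a gene, and the changes turned to -0.0296 for Acta2 (ovalbumin, C57BL/6), -0.17 for Igkv9-120 (resiquimod, A/J), and 0.14 and 0.26 for Hbb-b2 (resiquimod against ovalbumin and against PBS, A/J).

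With each array left out in turn the counts ran from 680 to 1495 (ovalbumin, A/J), 260 to 527 (ovalbumin, C57BL/6), 2259 to 3649 (resiquimod, C57BL/6), 2373 to 3665 (resiquimod against PBS, A/J) and 138 to 636 (difference in the resiquimod effect). The overlaps for ovalbumin ran from 135 to 241 and from 5 to 20 genes, the genes raised by ovalbumin and lowered by resiquimod within A/J from 131 to 219 and the lists for the difference in the ovalbumin effect from 7 to 14 (7 without A/J ovalbumin 3). The alternatives for a linear table had no use, as the table is on the log2 scale.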

Other observations

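The tests of the lists in this part were planned, and the genes named follow the rule chosen before the data were examined. Genes induced by glucocorticoids and metals changed after resiquimod in A/J, where 7 of 14 rose (9 adjusted over the list alone), such as the metallothionein Mt2 (0.90 ± 0.18) and the siderophore-binding Lcn2 (1.20 ± 0.15), with adjusted p = 0.0902 with an estimated correlation. A/J ovalbumin 1 and A/J resiquimod 3 held liver transcripts, and no C57BL/6 array did. In C57BL/6 1 of the 14 rose and 1 fell (1 and 2 adjusted over the list alone). The difference between the strains passed limma's test for 1 member (6 adjusted over the list alone) and lost its camera call with adjusted p = 0.206 with an estimated correlation. Of the circadian clock list 4 of 16 genes fell and 1 rose in A/J after resiquimod (5 and 1 adjusted over the list alone) and 4 fell in C57BL/6 (7 lower and 1 higher adjusted over the list alone), including the clock repressor Bhlhe40 (-0.97 ± 0.08 and -0.67 ± 0.08). The list lost its C57BL/6 camera call with adjusted p = 0.221 with an estimated correlation. The labels give no time of day.

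After resiquimod 4 of 15 heart muscle genes fell and 1 rose in A/J (5 and 1 adjusted over the list alone). In C57BL/6 8 fell (10 lower and 1 higher adjusted over the list alone), including the contractile genes Tnnc1 (-1.52 ± 0.22 and -1.77 ± 0.22) and Myl7 (-1.14 ± 0.21 and -1.46 ± 0.21). Their adjusted p were 0.493 and 0.269 with an estimated correlation. In A/J 2 of 3 ovalbumin and 1 of 3 resiquimod arrays held squamous epithelium transcripts, and in C57BL/6 1 of 3 in each of these groups. As background, heart muscle cells also line the large pulmonary veins of mice. Plasma cell genes rose in 3 of 14 cases in A/J (7 adjusted over the list alone), led by Mzb1 (2.69 ± 0.40), with adjusted p = 0.380 with an estimated correlation. In C57BL/6 4 rose and 1 fell (6 and 1 adjusted over the list alone), with adjusted p = 0.412 with an estimated correlation. In the xenobiotic and redox list Cyp1a1 fell in A/J (-2.00 ± 0.53) and in C57BL/6 (-1.87 ± 0.53). Of the 18 fits without 1 array 6 and 5 lost these calls. The synthesis enzyme of glutathione, Gclc, fell in both (-0.73 ± 0.11 and -0.76 ± 0.11). The ciliated cell list had 6 of 20 genes lower in C57BL/6 after resiquimod (7 adjusted over the list alone), with adjusted p = 0.316 with an estimated correlation.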
